A study of Mus musculus with 12 samples.

How the data were processed

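Gene expression was measured on 12 single-colour microarrays of RAW264.7 cells, a mouse macrophage line. The 4 groups held 3 arrays each, as the labels name them: control siRNA, control siRNA with LPS, siRNA against lincRNA-Tnfaip3, and that siRNA with LPS. Per the labels' protocols, cells received the siRNA for 24 h and were then cultured for a further 4 h with or without E. coli LPS at 1 µg/ml, and total RNA was labelled with Cy3. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

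Spot intensity values, with no normalization between arrays, were deposited as the output of Agilent Feature Extraction, version 10.7.1.1 per the file headers; the submitters' processing notes name the same tool without a version. Per the file headers, the processed intensity was background-subtracted and detrended within each array, and probe positions refer to mm9. The flags of each spot (outlier, saturation, well above background) were set by that software, per the file headers. Each column of the authors' value table was matched to its own array by rank (lowest rank correlation 0.999962), and its scale was read as log2 because the slope on the log2 signal of that array was 0.984 to 1.03. Every column of that table had a median of 4.75, so its columns share a common median. How it was normalized is not given in the sources used here, and it served only as an alternative.

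Each array held 59305 non-control spots of 55681 probes. No spot was saturated, and 104 to 258 spots per array carried an outlier flag and were left out, which left 102 missing values among the probes kept. Spots of 1 probe were averaged, values were taken as log2 of the processed intensity minus the array's 75th percentile, and a probe was kept if it was well above background on all 3 arrays of at least 1 group (33132 probes, 59.5%). For each gene the probe with the highest mean over the 12 arrays was used. Of the tested genes, 6109 had more than 1 kept probe, and where another probe of a named gene gave a different direction its value is stated. Accessions of 26582 probes matched the gene table of assembly GRCm38.p6, which was used for names only and updated 2892 symbols. The 23890 features tested comprised 13798 with a gene symbol and 10092 clones, loci, lincRNA regions or unnamed probes. Where no probe of a gene was well above background on any array of the dimmer group, the fold is given as "at least", the mean of the brighter group against, for each array of the dimmer group, the higher of the probe's own signal and the lowest signal among probes well above background. For the average over LPS states this was done in each state and averaged on the log2 scale, and a size is left out where no difference remained.

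One linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, so that all groups shared 1 estimate of spread with 8 residual degrees of freedom. The contrasts were LPS in control-siRNA cells, the lincRNA siRNA in LPS-stimulated and in unstimulated cells, LPS in lincRNA-siRNA cells, and the interaction. Adjusted p-values were computed by the Benjamini-Hochberg method over all features of a contrast with a threshold of 0.05, and errors of log2 changes are standard errors of that model. LPS-induced and LPS-repressed genes were chosen by the LPS effect averaged over both siRNAs (adjusted p under 0.05 and at least 2-fold). That average uses the same arrays as the contrasts between siRNAs. With equal group sizes, and if all arrays have equal spread, it is uncorrelated with them. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with the estimated correlation. Input was read with version 1.17.8 of the R package data.table, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

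The contrasts, tests, alternatives and gene lists were fixed before the data were examined. The lists covered inflammatory cytokines, chemokines, NF-kB subunits and feedback, interferon-stimulated genes, TLR4 signalling, immediate-early genes and MAPK feedback, inflammatory effectors, inflammasome and cell death, antigen presentation, sensing of double-stranded RNA, cell cycle, p53 targets, glycolysis and hypoxia, cholesterol synthesis, LXR and PPAR lipid handling, the unfolded protein response, heat shock, NRF2 targets, alternative activation, macrophage identity, osteoclast and dendritic cell genes, markers of other cell types, ribosomal proteins and housekeeping controls. Named genes were the 10 highest and 10 lowest log2 changes of a contrast (5 and 5 for LPS in lincRNA-siRNA cells and for the interaction) among symbols that passed the threshold with no overlap between the groups' arrays, the largest changes of each list, and Tnfaip3. The effect of the siRNA averaged over both LPS states, its 5 highest and 5 lowest genes, and the test of the LPS-responsive sets in unstimulated cells and in the interaction were added after the data were examined.

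The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median of bright probes, the authors' table, no filter on dim probes or a filter on all 12 arrays, the replicate number as a block, the slide as a block, a fit of only the groups compared, an intensity trend with robust fitting, array weights, the mean of all probes of a gene, a threshold of at least 2-fold, LPS genes chosen in control-siRNA cells alone, and each array left out in turn. A further 4 fits were chosen after the data were seen: the slide as a random effect, slide 2 alone, the fit without the 2 arrays of slide 1, and the fit without 3 arrays that deviated together. These alternatives chose the LPS-responsive genes anew; the slide-blocked values in the report keep the genes of the main fit, a choice made after the data were seen.

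The procedure was tested on simulated data in which, per contrast, 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 23890 features. Noise was normal with each gene's measured spread, independent between genes and arrays, and without slide differences. In the real data slides differ between groups, so the shares below are not the power of the real contrasts. At a 2-fold change it recovered 37.3% of changed genes for LPS in control-siRNA cells, 50.7% and 38.8% for the siRNA in LPS-stimulated and unstimulated cells, 47.8% for LPS in lincRNA-siRNA cells and 20.9% for the interaction. At a 1.5-fold change these shares were 16.4%, 11.9%, 16.4%, 11.9% and 2.99%. For the averaged siRNA effect it recovered 49.3% at 2-fold and 38.8% at 1.5-fold.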

Results

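Expression of genes and long intergenic noncoding RNA regions was measured in RAW264.7 macrophages treated with a control siRNA or with an siRNA against lincRNA-Tnfaip3, each without or with LPS, the bacterial cell wall component that macrophages sense through TLR4. Each of the 4 groups had 3 arrays. The number of probes well above background was 27198 and 29462 on the first and second control-siRNA arrays and 32708 to 36367 on the other arrays. The 75th percentile of the processed signal was 312 to 478 across the 12 arrays. The number of arrays, 3 per group, limits the precision of every value.

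The arrays came from 3 slides, and the slides did not hold all groups. Slide 1 held control-siRNA arrays 1 and 2 only, and slide 3 held arrays 2 and 3 of the lincRNA siRNA with LPS only. Slide 2 held the other 8 arrays, among them all 3 arrays of control siRNA with LPS and all 3 of the lincRNA siRNA without LPS. Because slides 1 and 3 each held a single group, an estimate with the slide as a block rests on slide 2 and, for genes measured on all arrays, equals the estimate from slide 2 alone. It is given beside some of the results below. For the other named changes, the text gives how many passed with the block or names genes that did not.

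The first question was whether the siRNA lowered its target, and the arrays could not answer it. No probe carried the name lincRNA-Tnfaip3. On mm9, 8 probes lay within 500 kb of the Tnfaip3 probe on chromosome 10 (18720776 to 18720835), that probe included, and 0 of them targeted a lincRNA region. The reference table lists 7 long noncoding RNA genes within the same distance, of which 0 matched a probe by accession or symbol; positions were not compared, since that table uses another assembly. The group names therefore describe which siRNA was given, not a measured loss of the RNA.

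Tnfaip3, which encodes the NF-kB inhibitor A20, is the gene the siRNA target is named after. It rose with LPS by a log2 change of 1.35 ± 0.20 (SE, n = 3 per group, adjusted p = 0.00373) in control-siRNA cells and by 1.31 ± 0.20 (adjusted p = 0.00754) in lincRNA-siRNA cells. The slide-blocked changes were 1.45 (adjusted p = 0.0944) and 1.44 (adjusted p = 0.124). Between the siRNAs the Tnfaip3 difference was -0.41 with LPS (95% CI -0.85 to 0.02, adjusted p = 0.976) and -0.38 without LPS (95% CI -0.82 to 0.06, adjusted p = 0.316), and neither passed. Of the other genes near Tnfaip3, Hebp2 and Arfgef3 were well above background on all 12 arrays, Nhsl1 on 1, Gm4922 on 2 and the others on 0.

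The next comparison asked how control-siRNA cells responded to 4 h of LPS. Antiviral and inflammatory genes rose most. Mx1, an interferon-induced antiviral GTPase, rose by 7.80 ± 1.08 (log2, SE, n = 3 per group, adjusted p = 0.00281, at least 46.2-fold), and Il6, a cytokine of acute inflammation, rose by 6.85 ± 0.34 (adjusted p = 9.81e-06). Cish, a feedback inhibitor of cytokine receptor signalling, rose by 6.67 ± 0.83 (adjusted p = 0.00147). The guanylate-binding protein genes Gbp2 and Gbp2b rose by 5.99 and 5.90, Mx2 by 5.81, the alarmin gene Il33 by 5.67 (log2 at least 3.43, since its signal without LPS was not above background), Cmpk2 by 5.64, Ifi209 by 5.55 (at least 16.0-fold) and the RNA sensor gene Ifih1 by 5.23. Other probes of Ifi209 gave changes of 2.42 and 3.02. With the slide as a block Mx1, Cish and Ifi209 did not pass.

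Among genes that fell in control-siRNA cells, Myadml2 changed by -2.57 ± 0.57 (adjusted p = 0.0314), Lrrc17 by -2.16 ± 0.36 (adjusted p = 0.00771) and Usp2, a deubiquitinase gene, by -1.82. Gpr183, an oxysterol receptor gene, and Angpt2, an angiopoietin gene, each changed by -1.81. Nlrp10 changed by -1.65, Klhl6 by -1.59, Lrrc14b by -1.55 and Tmem51 by -1.5 ± 0.16 (adjusted p = 0.000593). Susd3 changed by -1.64, while another Susd3 probe gave 0.15. Of the genes in this paragraph only Susd3 and Tmem51 passed with the slide as a block.

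Of the 18 measured inflammatory cytokine genes, 15 rose in control-siRNA cells, 0 fell and 3 did not pass, and 17 rose when adjusted over the list alone. Besides Il6, the largest were the colony-stimulating factor genes Csf2 (5.22), Csf3 (4.42) and Csf1 (3.86), whose products drive myeloid growth. The list median was 2.52 (camera adjusted p = 3.88e-20; adjusted p = 0.00318 with an estimated correlation). Of 12 chemokine genes 7 rose, and 9 when adjusted over the list alone, with a median of 1.96 (camera adjusted p = 4.01e-09; adjusted p = 0.0142 with an estimated correlation). Cxcl10 rose by 4.82, Cxcl2 by 3.64, Ccl5 by 3.30 and Ccl2 by 3.06; these attract lymphocytes, neutrophils and monocytes.

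Interferon and interferon-stimulated genes were the group with the largest rise in control-siRNA cells. Of 38 measured, 36 rose, and all 38 when adjusted over the list alone, with a median of 3.83 (camera adjusted p = 2.13e-37; adjusted p = 0.0612 with an estimated correlation). Of 28 genes for NF-kB subunits, inhibitors and feedback, 14 rose and 0 fell (16 and 2 when adjusted over the list alone), with a median of 0.69 (camera adjusted p = 7.85e-08; adjusted p = 0.0554 with an estimated correlation). Socs1 (3.49) and Socs3 (1.58), inhibitors of cytokine signalling, and the NF-kB subunit gene Rel (2.51) rose beside Tnfaip3. The slide-blocked Rel change was 1.28 (adjusted p = 0.119).

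Of 29 immediate-early and MAPK feedback genes, 11 rose and 1 fell in control-siRNA cells (15 and 3 when adjusted over the list alone), among them the stress-induced factor gene Atf3 (1.94) and the phosphatase gene Dusp5 (1.59). Their median was 0.61 (camera adjusted p = 1.74e-06; adjusted p = 0.0140 with an estimated correlation). Of 23 antimicrobial and inflammatory effector genes 11 rose (12 up and 2 down when adjusted over the list alone), with a median of 0.78 (camera adjusted p = 1.05e-06; adjusted p = 0.0209 with an estimated correlation). Ptgs2, which encodes cyclooxygenase 2, rose by 2.57, the acute-phase gene Saa3 by 2.50, the protease inhibitor gene Slpi by 2.48 and Nos2, the inducible nitric oxide synthase gene, by 1.93. Of 22 antigen presentation and costimulation genes 6 rose, and 16 when adjusted over the list alone, with a median of 0.57 (camera adjusted p = 5.83e-07; adjusted p = 0.0140 with an estimated correlation). Cd40, a costimulatory receptor gene, rose by 3.01 and the peptide transporter gene Tap1 by 1.94. Of 27 inflammasome and cell death genes 6 rose (9 up and 2 down when adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.00619; adjusted p = 0.0392 with an estimated correlation). They included the death receptor gene Fas (1.98), the inflammasome sensor gene Nlrp3 (1.85) and Bcl2l11 (1.5), which encodes a pro-apoptotic protein.

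Of 25 TLR4 signalling genes 1 rose and 1 fell in control-siRNA cells (2 and 1 when adjusted over the list alone). Irak3, which restrains TLR signalling, rose by 0.90 ± 0.09 (adjusted p = 0.000363), and the receptor gene Tlr4 itself changed by -0.68 ± 0.12 (adjusted p = 0.0112). Ticam2 (0.96, adjusted p = 0.147) and Cd14 (0.92, adjusted p = 0.0749) did not pass. The list median was -0.07 and the camera direction was down (adjusted p = 0.812), while the mean was 0.05. Of 18 genes for double-stranded RNA sensing and RNA interference 7 rose (7 up and 1 down when adjusted over the list alone), among them Ifih1 and the sensor gene Ddx58 (3.39); the list median was 0.04 (camera adjusted p = 0.105).

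Lists of growth and lipid genes were also tested with LPS in control-siRNA cells. Of 32 cell cycle and DNA replication genes 4 fell (6 when adjusted over the list alone), with a median of -0.19 (camera adjusted p = 6.13e-08; adjusted p = 0.0612 with an estimated correlation). The mitotic kinase gene Aurkb changed by -1.22 (adjusted p = 0.0394) and by -0.60 with the slide as a block (adjusted p = 0.385), and E2f2 by -0.66. Of 23 cholesterol synthesis and uptake genes 1 fell and 7 when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 4.79e-06; adjusted p = 0.137 with an estimated correlation); Mvd and Cyp51, each at -0.59, did not pass (adjusted p = 0.0647 and 0.138). Of 18 LXR and PPAR lipid handling genes 1 rose and 3 fell (1 and 5 when adjusted over the list alone). Fabp4, a fatty acid carrier gene, rose by 2.27 and Abcg1, a cholesterol exporter gene, changed by -1.07; the list median was -0.12, the mean 0.00 and the camera adjusted p 0.0797.

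The remaining lists held few passing genes in control-siRNA cells. The numbers that rose and fell were 1 and 2 of 15 p53 target genes (median -0.27, camera adjusted p = 0.0911) and 0 and 1 of 24 glycolysis and hypoxia genes (median -0.04, mean 0.02, adjusted p = 0.546). Of 11 alternative activation genes 1 rose, Ccl24 (2.38, and 1.45 with the slide as a block, adjusted p = 0.254), with a list median of 0.27 (adjusted p = 0.812). Of 20 unfolded protein response genes 2 rose, among them Ppp1r15a (0.73; list median 0.09, adjusted p = 0.812), of 12 osteoclast genes 2, among them Mmp9 (1.32; median 0.12, adjusted p = 0.812), and of 9 dendritic cell genes 1, Cd83 (1.16; median 0.55, adjusted p = 0.0911). None passed among 9 heat shock genes (median 0.18, adjusted p = 0.383), 15 NRF2 targets (0.00, adjusted p = 0.710), 20 macrophage identity genes (0.09, adjusted p = 0.546) and 12 housekeeping genes (0.14, adjusted p = 0.796). Of 10 measured markers of other cell types 1 rose; the median was 0.67 (camera adjusted p = 0.0214; adjusted p = 0.270 with an estimated correlation) and 0.18 with the slide as a block (adjusted p = 0.0758). None of 19 ribosomal protein genes passed; their median was 0.23 (camera adjusted p = 0.0344; adjusted p = 0.703 with an estimated correlation) and -0.04 with the slide as a block (adjusted p = 0.575).

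In all, 1231 of 23890 features passed in control-siRNA cells, 780 higher and 451 lower, and 566 of them changed at least 2-fold (516 higher, 50 lower). Blocking on the slide left 233 features, of which 84.1% were higher against 63.4% without the block, and 42 passed within slide 2 alone. The count was 537 to 3975 when 1 array was left out, with the highest value without control-siRNA array 3. In that fit the control-siRNA arrays without LPS came from slide 1 and those with LPS from slide 2. Slide and LPS cannot be told apart there. All 53 named changes kept their direction with the slide as a block, and 27 of them passed. For the highest and lowest genes, chosen for no overlap between the groups' arrays, the direction was fixed in advance. Those that did not pass included Ccl2, Saa3, Nos2, Tap1, Ddx58, Tlr4 and Fabp4. Within slide 2, where 3 LPS arrays stand against 1 control array, the list medians were 2.41 for cytokines, 1.52 for chemokines, 3.78 for interferon-stimulated genes and 0.62 for NF-kB genes. With 1 control array the spread of that group is not measured. Over all slides the last 2 lists had adjusted p = 0.0612 and 0.0554 with an estimated correlation.

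**Figure D1:**
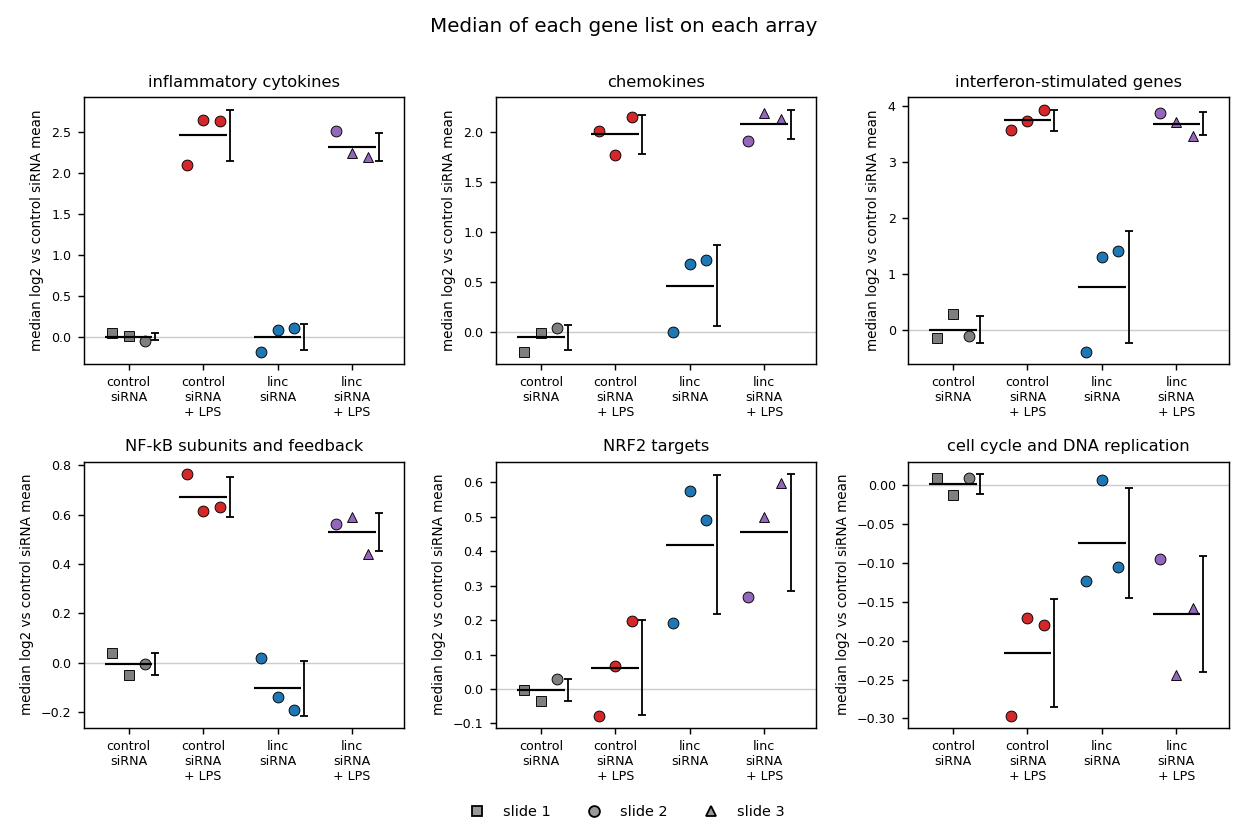
Median of the members of 6 gene lists on each array, as log2 change from the mean of the control-siRNA arrays; each point is 1 array (square slide 1, circle slide 2, triangle slide 3), lines are group means and bars the SD of 3 arrays. The interferon-stimulated genes stood at 3.47 to 3.94 on the LPS arrays, at 1.30 and 1.41 on lincRNA-siRNA arrays 2 and 3 without LPS, and at -0.39 on array 1 of that group.

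LPS was then compared within lincRNA-siRNA cells. The same kinds of genes rose. Cish rose by 6.05 ± 0.83 (log2, SE, n = 3 per group, adjusted p = 0.0045), Il6 by 6.01 ± 0.34 (adjusted p = 2.61e-05), Il33 by 6.0 ± 0.47 (at least 17.2-fold), Mx1 by 5.91 ± 1.08 (adjusted p = 0.0231) and Gbp2b by 4.98. Prtg changed by -1.71 ± 0.22 (adjusted p = 0.00273), Gpr176 by -1.22, Tmem51 by -1.13 and Pira2 by -1.10. Slc9b1 changed by -1.32, while another Slc9b1 probe gave 0.07. With the slide as a block Cish, Mx1 and all the genes named here that fell did not pass.

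Of the 18 cytokine genes 12 rose in lincRNA-siRNA cells (16 when adjusted over the list alone; median 1.60, camera adjusted p = 1.10e-34), among them Csf2 (4.46), Lif (4.03), a cytokine of the interleukin 6 family, and Csf3 (3.74). Of the 12 chemokine genes 4 rose (7 when adjusted over the list alone; median 1.2, adjusted p = 7.88e-13), among them Cxcl10 (4.75), Ccl5 (3.03) and Cxcl2 (2.78). Of the 38 interferon-stimulated genes 24 rose (34 when adjusted over the list alone; median 2.76, adjusted p = 4.91e-52), among them the antiviral gene Rsad2 (4.76), Mx2 (4.66) and Cmpk2 (4.47). Of the 28 NF-kB genes 11 rose (14 when adjusted over the list alone; median 0.57, adjusted p = 4.82e-17), among them Socs1 (3.35), Socs3 (1.74) and the kinase gene Ikbke (1.33). These 4 lists also passed with an estimated correlation (adjusted p = 0.000431, 0.00354, 0.0281 and 0.00577).

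Atf3 (1.67) and Dusp5 (1.49) were among 7 of 29 immediate-early genes that rose in lincRNA-siRNA cells, and Cd40 (2.47) and Tap1 (1.63) among 5 of 22 antigen presentation genes. Ptgs2 (2.24) and Slpi (1.84) were among 6 of 23 effector genes, while Saa3 (2.12, adjusted p = 0.0615) did not pass. Nlrp3 (1.77), Fas (1.69) and Bcl2l11 (1.27) were among 6 of 27 inflammasome and cell death genes. Of the cell cycle list 0 genes passed, with a median of -0.12 (camera adjusted p = 0.00175; adjusted p = 0.290 with an estimated correlation), and -0.05 with the slide as a block (adjusted p = 0.289). Of the cholesterol list 0 passed, with a median of -0.18 (camera adjusted p = 0.00113; adjusted p = 0.290 with an estimated correlation). Of the dendritic cell list 1 passed, with a median of 0.31 (camera adjusted p = 0.0252; adjusted p = 0.0848 with an estimated correlation; with the slide as a block 0.55, adjusted p = 0.152).

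In lincRNA-siRNA cells 443 features passed, 360 higher and 83 lower, and 271 changed at least 2-fold (260 higher, 11 lower). Blocking on the slide left 158. All 32 named changes kept their direction and 17 passed with the block. For the highest and lowest genes, again chosen for no overlap between arrays, that direction was fixed in advance. The count fell to 246 without array 2 of the lincRNA siRNA with LPS. The LPS contrasts of both siRNAs share no array. They had 345 higher features in common (11.8 expected for independent lists) and 74 lower (1.57 expected), and the change had the same sign in the other siRNA for 97.6% of features higher and 98.7% of features lower with control siRNA. Across genes, which are not independent replicates, the changes correlated with r = 0.584. The smaller count with the lincRNA siRNA is not a test of a difference, which the interaction gives.

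**Figure D2:**
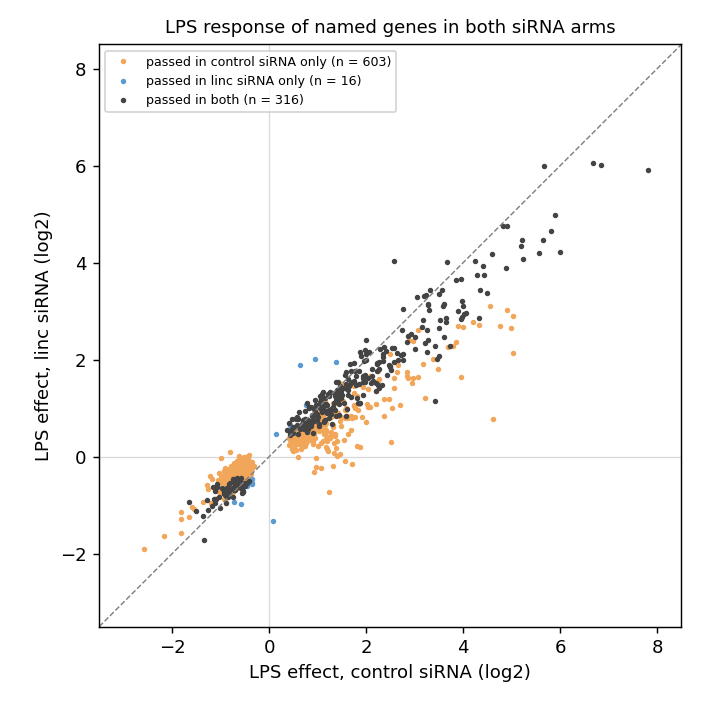
Log2 change with LPS in control-siRNA cells (horizontal axis) and in lincRNA-siRNA cells (vertical axis) for the 935 named genes that passed in at least 1 of them; each point is a gene. Of these, 316 passed with both siRNAs, 603 with control siRNA only and 16 with the lincRNA siRNA only.

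The main question was whether the lincRNA siRNA changed the response of LPS-stimulated cells, and no gene passed. Il6 differed by -0.22 (log2, 95% CI -0.99 to 0.55, n = 3 per group, adjusted p = 0.987) and Tnf, the other classical inflammatory cytokine gene, by -0.03 (95% CI -0.26 to 0.19, adjusted p = 0.997). Csf1 differed by -0.63 (95% CI -0.99 to -0.28, adjusted p = 0.905) and Il1b, an inflammasome-processed cytokine gene, by -0.56 (95% CI -0.93 to -0.20, adjusted p = 0.946). Gbp3 (-0.90), Gbp2 (-0.57) and Socs3 (-0.49) did not pass either (each adjusted p = 0.976). These intervals are unadjusted and leave differences of the sizes they span open.

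NRF2 targets, genes of the antioxidant response, were shifted between the siRNAs with LPS. Their median was 0.31 (camera adjusted p = 1.91e-09; adjusted p = 0.138 with an estimated correlation), 0 of 15 passed over all genes and 5 were higher when adjusted over the list alone. Values were 1.51 ± 0.45 for Nqo1 (at least 1.82-fold, adjusted p = 0.974), 0.85 ± 0.11 for Taldo1 (adjusted p = 0.154), 0.65 ± 0.13 for Srxn1 (adjusted p = 0.483) and 0.44 ± 0.13 for Gclm (adjusted p = 0.974). The slide-blocked list median was 0.22 (adjusted p = 0.0150), and within slide 2 alone the test gave an adjusted p of 0.0550. Housekeeping genes had a median of 0.13 in the same contrast (camera adjusted p = 0.0962) and 0.12 within slide 2. The slide-blocked values rest on 1 lincRNA-siRNA array with LPS.

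The cytokine list had a median of -0.17 between the siRNAs with LPS (camera adjusted p = 0.0133; adjusted p = 0.538 with an estimated correlation), with 0 of 18 genes passing and 1 lower when adjusted over the list alone. Its slide-blocked median was -0.05 (adjusted p = 0.378). The heat shock list (median 0.19) and the unfolded protein response list (0.22) each had a camera adjusted p of 0.00654 and an adjusted p of 0.538 with an estimated correlation; with the slide as a block each had an adjusted p of 0.243. The medians were 0.00 for interferon-stimulated genes (adjusted p = 0.336), -0.10 for NF-kB genes (adjusted p = 0.188) and 0.05 for chemokines (adjusted p = 0.827). With limma, 0 features passed and 1108 had an unadjusted p under 0.05, against 1194.5 expected by chance; the smallest adjusted p was 0.0862. With the slide as a block 2 features passed.

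The 476 LPS-induced genes and the 34 LPS-repressed genes were tested as sets. In LPS-stimulated cells the induced genes had a median difference of -0.07 between the siRNAs, with 293 lower and 183 higher (camera p = 0.000433; p = 0.376 with an estimated correlation). For the same 476 genes the median was 0.00 with the slide as a block, and the camera test did not pass. The repressed genes had a median of -0.19, with 25 lower and 9 higher (camera p = 0.000115; p = 0.230 with an estimated correlation), and -0.18 for the same genes with the slide as a block (camera p = 0.0105; p = 0.441 with an estimated correlation). With 1 array left out, the medians of these genes were -0.17 to -0.01 for the induced and -0.30 to -0.11 for the repressed set. No member of either set passed over all genes; 2 induced genes and 1 repressed gene passed when adjusted over the set alone.

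**Figure D3:**
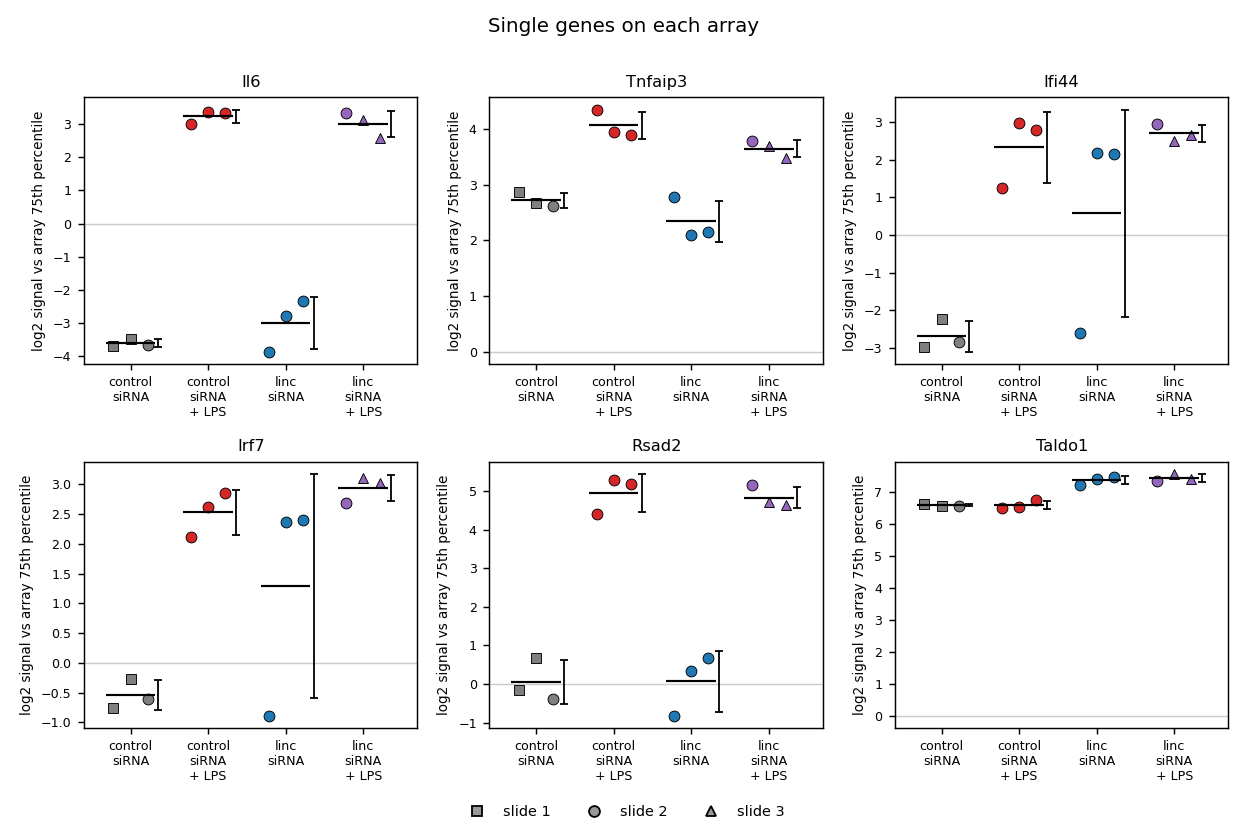
Log2 signal relative to the array's 75th percentile for Il6, Tnfaip3, Ifi44, Irf7, Rsad2 and Taldo1; each point is 1 array (square slide 1, circle slide 2, triangle slide 3), lines are group means and bars the SD of 3 arrays. With LPS, Il6 differed by -0.22 and Tnfaip3 by -0.41 between the siRNAs, while Ifi44 was high on only 2 of the 3 lincRNA-siRNA arrays without LPS.

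The siRNAs were also compared in unstimulated cells, where again no gene passed. Interferon-stimulated genes had a median difference of 0.86 between the siRNAs (camera adjusted p = 6.18e-05; adjusted p = 0.582 with an estimated correlation), with 0 of 38 passing over all genes and 0 when adjusted over the list alone. Ifi44, an interferon-induced gene, differed by 3.26 ± 1.09 (SE, n = 3 per group, adjusted p = 0.221), Oasl2 by 2.27 ± 0.91 and Usp18, a negative regulator of interferon signalling, by 1.94 ± 0.80. The list medians of the 3 lincRNA-siRNA arrays were -0.39, 1.30 and 1.41 against -0.15, 0.28 and -0.11 of the control arrays, so array 1 lay below all controls. Their slide-blocked median was 0.84, which compares these 3 arrays with control-siRNA array 3 only. Markers of other cell types had medians of 0.15, 0.59 and 0.89 on the same lincRNA-siRNA arrays and -0.17, 0.12 and 0.25 on the controls (list median 0.49, camera adjusted p = 0.153, and 0.14 within slide 2).

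NRF2 targets had a median of 0.37 between the siRNAs in unstimulated cells (camera adjusted p = 0.00420; adjusted p = 0.582 with an estimated correlation), and 6 were higher when adjusted over the list alone. Ftl1, a ferritin gene, differed by 0.83 and within slide 2 by 0.12, Taldo1 by 0.78 (adjusted p = 0.130; 0.81 within slide 2), Srxn1 by 0.75 (adjusted p = 0.170; 0.62) and the cystine transporter gene Slc7a11 by 0.59 (0.89). Hmox1, outside the naming rule, stood at -2.44, 0.80 and 1.01 on the 3 lincRNA-siRNA arrays, and Gclc at -0.16, -0.10 and -0.22. The slide-blocked median was 0.23. Slide-blocked values in unstimulated cells compare the 3 lincRNA-siRNA arrays with control-siRNA array 3 only, and their p-values use the preset correlation. Housekeeping genes had a median of 0.32 (adjusted p = 0.167) and 0.04 within slide 2. Heat shock genes had a median of 0.31 (adjusted p = 0.0145; adjusted p = 0.582 with an estimated correlation), with Hspa8 at 0.91 (other probes 0.24 to 0.39; 0.13 within slide 2) and Hspd1 at 0.50 (0.19 within slide 2), and 0.14 with the slide as a block (adjusted p = 0.0274; within slide 2 alone 0.0608). Ribosomal protein genes had a median of 0.33 (adjusted p = 0.00941; adjusted p = 0.582 with an estimated correlation) and 0.01 with the block (adjusted p = 0.940). TLR4 genes had a median of -0.16 and cell cycle genes of -0.07 (each adjusted p = 0.0442; adjusted p = 0.582 with an estimated correlation), and with the block -0.10 (adjusted p = 0.434) and -0.05 (adjusted p = 0.426).

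Chemokine genes had a median of 0.61 between the siRNAs in unstimulated cells (camera adjusted p = 0.229), with Cxcl2 at 1.27 (adjusted p = 0.206) and Ccl12 at 1.07 (adjusted p = 0.223; 0.33 within slide 2). The list stood at -0.01, 0.68 and 0.71 on the 3 lincRNA-siRNA arrays, and its median within slide 2 was 0.08. Cytokine genes had a median of 0.00 and a mean of 0.13 with a camera direction of down (adjusted p = 0.602); Il1rn, the interleukin 1 receptor antagonist gene, stood at 1.65 (1.1 within slide 2) and Lif at -1.32 (-0.81). The LPS-induced genes had a median of 0.42, with 358 higher and 118 lower (camera p = 5.87e-06; p = 0.262 with an estimated correlation), and 29 passed when adjusted over the set alone. The LPS-repressed genes had a median of -0.63, with 31 lower and 3 higher (camera p = 7.39e-13; p = 0.0418 with an estimated correlation), and -0.60 for the same genes with the slide as a block (camera p = 1.27e-09; p = 0.0978 with an estimated correlation). They stood at -0.08, -0.78 and -1.01 on the 3 lincRNA-siRNA arrays and at 0.05, -0.09 and 0.04 on the controls, so array 1 lay within the range of the controls. With 1 array left out, the median of the repressed genes was -0.95 (without lincRNA-siRNA array 1) to -0.45 (without array 3), and in 8 of the 12 fits the estimated-correlation test did not pass. The induced genes stood at -0.06, 0.58 and 0.69 on the lincRNA-siRNA arrays, and the slide-blocked median of the same genes was 0.31 (camera p = 9.25e-11; p = 0.144 with an estimated correlation). Their median with 1 array left out was 0.28 to 0.60, and they passed with an estimated correlation only without lincRNA-siRNA array 1 (p = 0.00881).

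With limma, 0 features passed in unstimulated cells, while 4428 had an unadjusted p under 0.05 against 1194.5 expected by chance; the smallest adjusted p was 0.0712. With the slide as a block 623 had an unadjusted p under 0.05 and 1 feature passed. Without control-siRNA array 3, the only control array on slide 2, 2608 features passed, and without lincRNA-siRNA array 1 there were 133. In that fit without array 3 the controls came from slide 1 and the lincRNA-siRNA arrays from slide 2, so slide and siRNA cannot be told apart.

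The interaction asked whether the LPS response differed between the siRNAs, and no gene passed. For Tnfaip3 it was -0.04 ± 0.28 (log2, SE, n = 3 per group, adjusted p = 0.988) and for Il6 -0.84 ± 0.49 (adjusted p = 0.891). Interferon-stimulated genes had a median of -0.97, a smaller rise with the lincRNA siRNA (camera adjusted p = 1.47e-07; adjusted p = 0.710 with an estimated correlation), and -0.94 with the slide as a block, where 2 of the 4 groups are 1 array each. Values were -2.89 for Ifi44, -2.05 for Oasl2 and -1.90 for Usp18 (each adjusted p = 0.891). Since the list differed by 0.00 with LPS and by 0.86 without, the unstimulated arrays carried this median.

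Cell cycle genes had an interaction median of 0.13 (camera adjusted p = 0.000218, and 0.555 with an estimated correlation). With the slide as a block, which rests on groups of 1 array, their median was 0.17. The p53 targets had 0.17 (adjusted p = 0.0461; adjusted p = 0.482 with an estimated correlation) and cholesterol genes 0.14 (adjusted p = 0.0189; adjusted p = 0.710 with an estimated correlation), and with the block their adjusted p was 0.265 and 0.280. No member of these lists passed. The LPS-induced genes had an interaction median of -0.49, with 398 lower (camera p = 8.11e-14; p = 0.0815 with an estimated correlation), and -0.30 for the same genes with the block (camera p = 4.29e-12; p = 0.123 with an estimated correlation). The LPS-repressed genes had 0.38, with 28 higher (camera p = 9.75e-07; p = 0.137 with an estimated correlation), and 0.34 for the same genes with the block (camera p = 0.00542; p = 0.404 with an estimated correlation). With 1 array left out, the medians of the same genes were -0.68 to -0.40 for the induced and 0.22 to 0.52 for the repressed set. Both sets passed with an estimated correlation only without lincRNA-siRNA array 1 (p = 0.00126 and 0.00765). With limma, 0 features passed and 895 had an unadjusted p under 0.05, and 358 features passed without control-siRNA array 3. That fit left control siRNA without LPS on slide 1 only, so a slide difference cannot be told apart from an interaction.

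Averaged over both LPS states, a comparison added after the data were examined, 37 features differed between the siRNAs, 18 higher and 19 lower with the lincRNA siRNA. Hook1, which encodes a microtubule-binding adaptor, was higher by 1.51 ± 0.19 (log2, SE, 6 arrays per side, adjusted p = 0.0306). Its estimated difference was 2.50 without LPS (at least 0.91) and 0.53 with LPS (at least 0.38). The averaged log2 was at least 0.64, since Hook1 was above background on 0 of 3 control arrays without LPS and 2 of 3 with LPS. Taldo1, an enzyme gene of the pentose phosphate pathway, was higher by 0.81 ± 0.08 (adjusted p = 0.0306), the mitochondrial topoisomerase gene Top1mt by 0.75, Cnnm2 by 0.94 and Srxn1, the sulfiredoxin gene, by 0.70 ± 0.09 (adjusted p = 0.0308). Btnl10 was lower (adjusted p = 0.0478) by an amount that cannot be given, because it was above background on 0 of the 6 lincRNA-siRNA arrays and 1 of 3 unstimulated control arrays. Hacd4 differed by -0.86, the splicing factor gene Sf3b1 by -0.74, Itpka, an inositol phosphate kinase gene, by -0.65 and the actin regulator gene Cfl2 by -0.61. All 37 had the same direction in both LPS states, which choosing them by the average favours. Estimated sizes were unlike for some, as for Serpina5 (-2.33 with LPS and -0.07 without). No feature passed in the interaction, which tests such a difference (smallest adjusted p = 0.891). Of the 37, 33 were above background on all 12 arrays.

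Of the 15 NRF2 targets 2 rose in this average, Taldo1 and Srxn1, and 10 were higher when adjusted over the list alone. Their median was 0.36 (camera adjusted p = 5.45e-06, and 0.428 with an estimated correlation) and 0.18 with the slide as a block. The blocked estimate rests on slide 2, where control siRNA and the lincRNA siRNA with LPS had 1 array each. Nqo1, not above background on any control array, stood at 1.02 (log2 at least 0.53, adjusted p = 0.201). Housekeeping genes had a median of 0.24 (adjusted p = 0.0778) and 0.08 within slide 2. Heat shock genes had a median of 0.27 (camera adjusted p = 0.00314, and 0.60 with an estimated correlation) and 0.18 with the block. When adjusted over the list alone, 6 of them were higher. Tnfaip3 differed by -0.40 ± 0.14 (adjusted p = 0.229) and Il6 by 0.20 (adjusted p = 0.688). With the slide as a block 0 features passed, and 0 to 1625 passed when 1 array was left out. The 1625 came without control-siRNA array 3, which left control siRNA without LPS on slide 1 only. Slide and siRNA cannot be told apart in the unstimulated cells of that fit. The 10 named genes kept their direction with the block, which their choice for no overlap between the arrays had fixed in advance.

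The siRNA differences with and without LPS, which share no array, correlated across genes with r = 0.320, and with r = 0.187 within slide 2. Genes are not independent replicates, and 8 of 100 assignments of the siRNA labels within each LPS state gave a correlation at least as high.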

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

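The tests of slides, mixed-in RNA, wrong labels and the siRNA itself were chosen after the results were seen; the counts over other splits of the arrays were planned before the data were examined, except that the averaged siRNA effect they were also applied to was added later.

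For 4 gene lists the LPS response differed between the siRNAs by camera on the interaction. The median log2 interaction was -0.97 for interferon and interferon-stimulated genes, 0.13 for cell cycle and DNA replication, 0.17 for p53 targets and 0.14 for cholesterol synthesis and uptake. None of the 4 passed with an estimated correlation (adjusted p = 0.710, 0.555, 0.482 and 0.710).

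In unstimulated cells 4428 features had an unadjusted p under 0.05 between the siRNAs, and 623 with the slide as a block or 602 within slide 2. If slides were the cause, the slide 2 control array should differ from the slide 1 controls as the lincRNA-siRNA arrays do. The correlations across genes, between differences that share no array, were 0.290 and 0.452. Both were positive, as a shared slide shift would give. They rest on 1 control array of slide 2 and lie between the levels set for and against this cause, so they do not decide. If the siRNA were the cause, changes measured with different arrays and against controls of different slides should correlate. Their median correlation was 0.0802 (-0.161 to 0.163). These differences rest on single arrays, whose spread within a group can hide a common change, so the values do not decide. Slide and siRNA cannot be told apart here, because 2 of the 3 control arrays were alone on slide 1.

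Interferon-stimulated genes were high on 2 of the 3 unstimulated lincRNA-siRNA arrays. Mixed-in RNA from an LPS-treated culture should give every gene a like share of its LPS rise, but the upper quartile of the shares was at least 8.47 times the lower, with Ifi44 at 90.1% and 87.9% and Ifit1 at 0.903% and 2.54%. An LPS-treated sample under the wrong label is argued against by the cytokines, whose median share reached at most 4.61%, and a slide difference by a range of 1.79 in the list median among 3 arrays of slide 2. Median shares on these 2 arrays were higher for chemokines (23.0% and 21.7%) and effector genes (13.8% and 14.7%). The shift was thus not confined to interferon-stimulated genes. Among unstimulated arrays, markers of other cell types were also highest on these 2 (0.59 and 0.89 against -0.17 to 0.25), so RNA from other cells is not excluded. That list also had a higher median with LPS in control-siRNA cells. Between the siRNAs without LPS its median was 0.14 within slide 2. A higher list median therefore need not mean other cells. The siRNA itself stays open, since 2 of its 3 arrays but not the other lay above all controls, and so does an untested exposure of those 2 cultures to interferon or to a weak or different stimulus.

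Of the 37 features that differed between the siRNAs on average, all kept their direction with the slide as a block, and the lowest ratio of blocked to unblocked change was 0.781 (median 0.996). The features were picked by the unblocked fit, which favours features whose arrays of a group are alike across slides. For 26 of them the arrays of the siRNAs did not overlap, which fixed the direction with the block. The ratios therefore do not test slides as the cause. None passed with the block, where the median SE was 0.111 against 0.0807, the residual degrees of freedom 6 against 8, and 1746 features against 4126 had an unadjusted p under 0.05; which of these ended the calls was not tested. Among 100 assignments of the siRNA labels within each LPS state, 2 gave as many features, the real one (37) included, a share under 0.05. The other gave 53 and, like the real labels, placed both slide 1 arrays on one side. Unlike the real labels, it also placed lincRNA-siRNA array 3 and array 2 of both LPS groups on one side. The next highest assignments, with 5 and 2 features, kept these arrays together too, and the one with 5 had the slide 1 arrays apart. What gave the 53 was not tested. Since slide 1 held control-siRNA arrays only, the share does not separate the siRNA from the slide.

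For the other contrasts the splits give these values. LPS in control-siRNA cells called 1231 features and the highest other split 16, with 1 of the 10 splits as large; for LPS in lincRNA-siRNA cells the values were 443, 183 and 1 of 10. With 10 splits, a share under 0.05 cannot be reached. For the siRNA the real count was 0 in LPS-stimulated cells (highest other 0), 0 in unstimulated cells (highest other 5) and 0 in the interaction (highest other 14 among 100 assignments). Every split reaches a count of 0, so for these 3 contrasts the splits test nothing.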

How the results depend on the processing

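The fits with the slide as a random effect, on slide 2 only, without the 2 arrays of slide 1 and without 3 arrays that deviated together were chosen after the data were seen; the other alternatives were planned. No called named gene reversed under any alternative; of 95 called named results the slide block ended 51 and slide 2 only 78. For LPS in control-siRNA cells (1231 features) the counts were 715 with no filter, 233 with the slide block, 633 with only the 2 groups compared, 5972 with array weights, 566 at 2-fold, 42 on slide 2 only, 209 without slide 1, 379 without the 3 arrays, and 537 to 3975 with 1 array left out; the share higher (63.4%) was 50.8% with the filter on all 12 arrays, 84.1% with the slide block and 90.4% without slide 1. For LPS in lincRNA-siRNA cells (443) they were 158 with the slide block, 139 with only the 2 groups, 271 at 2-fold, 45 on slide 2 only, 156 without the 3 arrays, and 246 to 470 with 1 array left out. For the siRNA in unstimulated cells (0) they were 5 with normexp, 1 with the slide block, 5 with a trend and robust fitting, 4333 with array weights, 2 with the mean of probes, 4 without slide 1, 9 without the 3 arrays, and 0 to 2608 with 1 array left out. For the siRNA with LPS (0) the slide block gave 2, and for the interaction (0) leaving out 1 array gave 0 to 358. For the averaged siRNA effect (37) they were 0 with no filter, 99 with the filter on all 12 arrays, 20 with the replicate block, 0 with the slide block, 104 with a trend and robust fitting, 898 with array weights, 4 at 2-fold, 22 with a random slide effect, 0 on slide 2 only, 1 without slide 1, 3 without the 3 arrays, and 0 to 1625 with 1 array left out. Fewer arrays or degrees of freedom lower the power, yet some of these fits gave more features. The counts of 3975, 2608, 358 and 1625 all came without control-siRNA array 3. That fit left control siRNA without LPS on slide 1 only. A slide difference cannot be told apart there from LPS or the siRNA. The causes of the shifts were not tested. Named genes chosen for no overlap between the groups' arrays could not reverse in fits on fewer arrays or with the slide as a block.

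With the set chosen anew in each fit, the LPS-induced genes in LPS-stimulated cells (-0.075) had -0.0058 with the slide block, -0.030 on slide 2 only and -0.075 with an estimated correlation (p = 0.376), and -0.17 to 0.0014 with 1 array left out; the LPS-repressed genes had -0.19 with an estimated correlation (p = 0.230). The 0.0014 for the LPS-induced genes, against -0.075 in the main fit, was a reversed sign. Signs also reversed for the Tnfaip3 interaction (-0.04). It was 0.10 in the authors' table, 0.11 with array weights and -0.16 to 0.18 with 1 array left out. Ribosomal protein genes with LPS in control-siRNA cells (0.23) had -0.038 with the slide block, on slide 2 only and without slide 1. The interaction of LPS-repressed genes (0.38), likewise chosen anew, had -0.038 without the 3 arrays. The causes were not tested. Whether replicate numbers pair the arrays is not given by the labels and was not settled by the values. Same-numbered deviations correlated at -0.299 to 0.469 over 18 pairs, 8 of them above 0.1, and 5 of 12 arrays matched best with their own number. With the replicate block 1575 features passed for LPS in control-siRNA cells. The fit of only the groups compared was not run for the interaction or the averages. Probes near background limit the fold changes given as "at least", and also others where only some arrays of the dimmer group were above background. With dim signals raised to the lowest signal well above background, Rel with LPS in control-siRNA cells went from 2.51 to 1.33 and Ccl24 from 2.38 to 1.15. Between the siRNAs in unstimulated cells, Il1rn went from 1.65 to 0.59.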

Other observations

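The tests reported here on lincRNA regions use the planned contrasts, and the summary by feature class was chosen after the results were seen.

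Of 3521 tested lincRNA-region features, 71 rose and 13 fell with LPS in control-siRNA cells, which is 2.39% against 5.63% of the other features. In lincRNA-siRNA cells 30 rose and 4 fell (0.966% against 2.01%), and 32 passed with both siRNAs. Among these 32, the largest rise in control-siRNA cells was on chromosome 2 at 128249388 to 128250301 (mm9), with 4.44 ± 0.38 in control-siRNA cells (log2, SE, adjusted p = 0.000151) and 2.75 in lincRNA-siRNA cells. Regions on chromosome 1 at 85304494 to 85305390 (3.63 and 2.73), chromosome 16 at 84708695 to 84708806 (3.59 and 2.93) and chromosome 11 at 119254413 to 119296960 (3.09 and 2.70) followed in that order, while in lincRNA-siRNA cells the chromosome 16 region was highest. Several rising features lay close together or overlapped on chromosome 1 between 175653557 and 175717250. Among them, features of opposite strand codes covered the same stretch, 175654606 to 175672031. The counts are therefore of features and not of separate RNAs. Between the siRNAs 0 lincRNA-region features passed with LPS and 0 without, and 1 was lower in the average. These regions were chosen after their values were seen.

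The first component of the spread within groups held 33.6% of it. Its highest loadings were 0.533 for lincRNA-siRNA array 3, 0.423 for array 2 of that siRNA with LPS and 0.321 for array 2 of control siRNA with LPS. The sign of a component is arbitrary, and the largest loading of the other sign was -0.339 for lincRNA-siRNA array 1. Arrays of the same slide had a consensus correlation of 0.153.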
